A study of Vitis rotundifolia with 36 samples.

How the data were processed

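Messenger RNA was sequenced from mature berries of muscadine grape (Vitis rotundifolia, also called Muscadinia rotundifolia), dissected into 4 tissue layers. The 36 libraries came from 3 cultivars, 4 layers and 3 replicates of each combination, which makes 12 groups. Per the labels' protocols, RNA was enriched for polyadenylated transcripts and turned into libraries with a directional kit, which keeps the strand of origin. Whether the reads were counted by strand is not given in the sources used here, so a count can include reads from an overlapping gene on the other strand.

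The deposited values are whole-number counts of reads per gene model, 1 table per library. Per the submitters' processing notes, cutadapt, STAR, SAMtools, HTSeq 0.11.2 and DESeq2 were used; the notes give no role or order for them, and the genome build and annotation are not given in the sources used here. Each table listed 26394 gene models, of which 22565 had at least 1 count in some library. The 5 special counter lines of each table were kept out of the library totals and of every test. Relative to the gene counts and the 5 special lines summed, reads outside any gene model came to between 7.733% and 14.56% per library. Ambiguous reads came to between 1.06% and 1.417%, and reads without a unique position to between 2.356% and 3.326%.

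The identifiers name a chromosome and a running number. None of them (0 of 26394) matched the reference gene table at hand, made from the Carlos assembly, and the files do not pair them with names or descriptions. Gene models are therefore given by identifier, with no coordinates, and 22 lists of genes fixed before the data were examined could not be run because they needed product descriptions. The rule for naming genes, also fixed then, took called gene models with the largest fold change, a mean of at least 10 CPM (the usual scaling of counts by the library total) on the higher side and every library of that side above every library of the other. Without names or descriptions it allowed at most 2 identifiers higher and 2 lower per comparison. Where the rule left fewer, the gene models with the smallest adjusted p were named instead, and the text says that they were chosen after their values were seen. Counts from members of gene families with near-identical sequences are uncertain, since reads can be split between copies or lost from them.

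Library totals ran from 19057538 to 61782400 counts. A floor of 3 counts, the most that a count of 0 allows at 95% confidence, corresponded to between 0.0423 and 0.144 CPM in a single library. Folds against a group whose 3 libraries all had 0 counts are given as lower bounds against a floor of 3 counts over the summed libraries of that group. Ratios against groups with 1 to 3 counts are given with a 95% counting interval. Floors and intervals cover counting error only.

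CPM values and log2 fold changes were computed here from the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM scaling of library sizes. Low counts were removed with the filterByExpr function by group, which left 19241 gene models. One negative binomial model with 12 group means was fitted to all 36 libraries with the default quasi-likelihood fit, leaving 24 residual degrees of freedom. Each contrast was tested with the quasi-likelihood F test and adjusted by the Benjamini-Hochberg method over all gene models tested. A gene model was called when its adjusted p was under 0.05 and its change was at least 2-fold. Layer contrasts were averaged over the 3 cultivars with equal weight. A gene model counted as enriched in a layer when it was called higher there than in each of the other layers. It counted as ordered with skin thickness when it was called between Alachua and Supreme and also changed the same way, with adjusted p under 0.05, between Alachua and Granny Val and between Granny Val and Supreme. The difference between Alachua and Supreme in the contrast of layers 2 and 3 was tested as an interaction. Standard errors are those of the fitted log2 fold changes.

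Principal components used log2 CPM with a prior count of 2. For the layer scores, gene models higher in layer 1 (399) or in layers 3 and 4 (307) than in the remaining layers were found in the Granny Val libraries by their labels. A library's score is its mean log2 CPM over such a set minus the mean of the Granny Val libraries, and each library was assigned to the nearest of the Granny Val means for layer 1, layer 2 and the inner layers. A set for layer 2 held only 12 gene models and was not used in the distances, a choice made after seeing that it would have changed the assignment of Alachua layer 1 replicate 1. The labels do not say whether replicates came from separate plants, clusters of fruit or extractions, so p-values measure only the spread between these libraries, which can be partly technical. No 2 libraries were identical (0 pairs), and the 36 pairs within groups differed by 94.94 to 1285 times the sampling variance.

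Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, no fold minimum, a replicate block, the series of library names as a covariate, only the 25 libraries whose names begin with a number, only the 9 libraries of a layer, and leaving out each library in turn. Added after the data were examined were a fit without the 6 libraries whose scores lay nearest another layer, a fit of the Granny Val libraries alone, and the newer quasi-likelihood fit of edgeR. Counts of called genes from both the default and the newer fit had been seen before the default, the fit named in the fixed design, was kept.

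The tests were run on simulated counts drawn with each gene model's mean share and spread and with the library sizes of the data. The changed gene models were drawn from those with a mean of at least 10 CPM, so the shares called do not cover lower levels. No other difference between cultivars or layers and no wrong label was simulated. For layer 1 against layer 2, with 18898 gene models tested, 37 of 100 gene models changed 2-fold and 91 of 100 changed 4-fold were called, with 5 false calls and 0 in the wrong direction. For Alachua against Supreme in layer 2, with 18873 tested, the calls were 12 of 100 and 67 of 100, with 3 false calls and 0 in the wrong direction. A call needs an estimated change of at least 2-fold, so a true 2-fold change lies at that limit. The median fitted log2 change of the gene models changed 2-fold was 1.01 between the layers and 0.94 between the cultivars. Their shares called are therefore lowered by the fold minimum as well.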

Results

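Gene expression was measured by RNA sequencing in mature muscadine berries, a grape with thick, leathery skin that separates from the pulp. The stated aim was to find genes connected with the thickness and texture of the skin, the firmness of the fruit and the slipping of the skin. The labels describe the skin of Alachua as thick, that of Granny Val as intermediate and that of Supreme as thin. Alachua and Supreme are purple and Granny Val is green. Layers were numbered from 1 to 4 from the outside of the berry inwards, with 3 libraries for each cultivar and layer. The protocol calls them epidermis with cuticle, hypodermis, mesocarp and endocarp, whereas the sample tags read cuticle, exocarp, endocarp and seed, so that only the layer numbers are used here. Totals lay between 19057538 and 61782400 counts per library.

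Principal component 1 held 31.3% of the variance and ran from layer 1, with 8 of the 9 libraries at or below -99.3, to layers 3 and 4. Component 2 held 10.2%. Pairs of libraries from 1 group had a median correlation of log2 CPM across gene models of 0.9127, and pairs from layers 3 and 4 of 1 cultivar had 0.9174. The medians were 0.8718 between layers 1 and 2, 0.8824 between layers 2 and 3 and 0.7962 between layers 1 and 3. Gene models are not independent replicates, so no test was made of these values. The layer scores take layers 3 and 4 together, so an exchange of labels between these could not be seen. By these scores, 18 of the 24 libraries of Alachua and Supreme lay nearest their labelled layer and 6 did not. Granny Val defined the scores and was not tested. The 6 were Supreme layer 1 replicate 1, Supreme layer 2 replicate 1, Alachua layer 2 replicate 3, Alachua layer 3 replicate 1 and Alachua layer 4 replicates 2 and 3. Each count of called gene models that moved by more than 1.5 times without these 6 libraries is given with that value. Lists of cultivar calls within that limit changed as well. For Alachua against Supreme, 59 of 85 calls were kept in layer 1 and 80 of 181 in layer 3. For Alachua against Granny Val, 560 of 585, 159 of 232 and 129 of 242 were kept in layers 1 to 3. For Granny Val against Supreme, 123 of 216 and 51 of 71 were kept in layers 1 and 2.

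**Figure D1:**
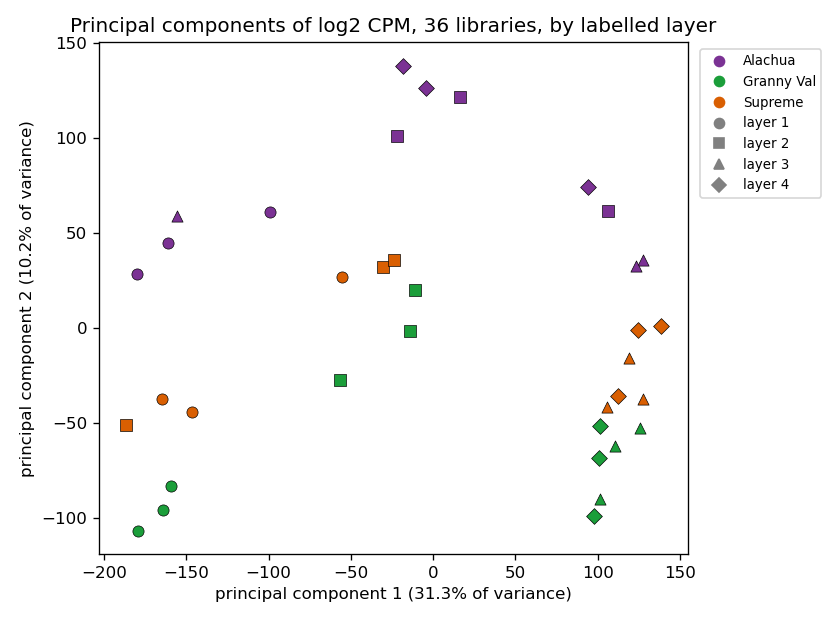
Principal components 1 and 2 of log2 CPM for the 36 libraries, with colour for the cultivar and shape for the labelled layer. Layer 1 lies to the left and most libraries of layers 3 and 4 to the right, with Alachua layer 3 replicate 1 at -155.6 on component 1 and Supreme layer 2 replicate 1 at -186.8.

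**Figure D2:**
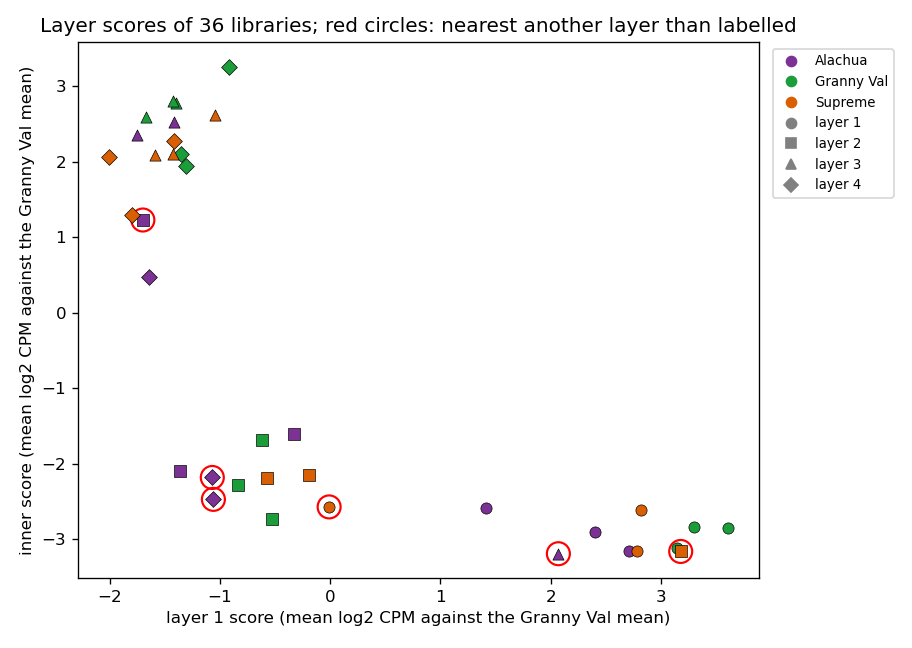
Layer 1 score (horizontal, log2 units) against inner score (vertical, log2 units) for each library, relative to the Granny Val mean. Red circles mark the 6 libraries nearest another layer than the labelled one, such as Supreme layer 2 replicate 1 with a layer 1 score of 3.18.

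The contrast of layer 1 with layer 2 asked which genes set the outermost tissue apart from the one beneath it. In layer 1, 560 gene models were higher and 368 were lower. Among those higher, evm.model.chr17.1130 on chromosome 17 had 110 ± 39.7 CPM in layer 1 and 28.2 ± 36.3 CPM in layer 2 (SD, n = 9 each). Its log2 fold change was 2.31 (SE 0.41, adjusted p = 0.0035), and without Supreme layer 2 replicate 1, at 123 CPM, the mean of layer 2 was 16.3 ± 7.62 CPM. Also higher was evm.model.chr11.1754, at 62.5 ± 25.6 against 21.1 ± 14.1 CPM. Both were chosen after their values were seen, because no higher gene model met the rule. Among those lower, evm.model.chr1.2009 had 2.67 ± 1.35 CPM in layer 1 and 11.3 ± 11.3 CPM in layer 2 (log2 fold change -1.97, SE 0.43, adjusted p = 0.0083). In layer 2, Alachua replicate 3, which is out of place, was at 41.4 CPM and the other libraries at 5.88 to 9 CPM. The level of evm.model.chr8.1635 was 16.3 ± 3.34 against 35.9 ± 13.8 CPM (log2 fold change -1.08). That change fell below 2-fold without Alachua layer 2 replicate 2 (adjusted p = 0.015), with the kind of library name as a covariate (log2 fold change -0.94, adjusted p = 0.0072) and in the 25 numbered libraries alone (-0.83, adjusted p = 0.022). The balance of directions was not stable, with 721 higher and 761 lower with no fold minimum and 481 and 497 in Granny Val alone, and the lower ones also outnumbered the higher ones without Alachua layer 2 replicate 2 or 3, Granny Val layer 1 replicate 3, Granny Val layer 2 replicate 1 or 2, or Supreme layer 2 replicate 2 or 3. The 928 calls were 4.82% of the gene models tested; without the 6 libraries out of place there were 2082, of which 899 were shared. Leaving out 1 library gave 472 calls without Alachua layer 1 replicate 3, 499 and 451 without Alachua layer 2 replicates 2 and 3, 540 and 468 without Granny Val layer 2 replicates 1 and 2, 507 and 509 without Supreme layer 1 replicates 2 and 3, and 1752, 391 and 363 without Supreme layer 2 replicates 1, 2 and 3.

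Between layers 2 and 3, across the boundary of the skin and the flesh as the protocol names them, 312 gene models were higher in layer 2 and 678 were lower. The largest named difference was evm.model.chr6.386, with 0.696 ± 0.91 CPM in layer 2 and 24.3 ± 13.9 CPM in layer 3 (SD, n = 9 each; log2 fold change -5.13, SE 1.17, adjusted p = 0.0084), and without Alachua layer 2 replicate 3 the mean of layer 2 was 0.463 ± 0.621 CPM. Its call was lost in the 25 numbered libraries alone (log2 fold change -7.05, adjusted p = 0.18) and in Granny Val alone (-4.99, adjusted p = 0.15). Lower in layer 2 as well was evm.model.chr1.1412, at 2.43 ± 1.58 against 13.2 ± 8.49 CPM (adjusted p = 0.016), whose call was lost in Granny Val alone (adjusted p = 0.21). Higher in layer 2 was evm.model.chr4.2376, at 49.7 ± 23.6 against 10.4 ± 11.8 CPM (log2 fold change 2.62, SE 0.33, adjusted p = 0.00028), chosen after its values were seen. Without Alachua layer 3 replicate 1 its mean in layer 3 was 6.82 ± 5.27 CPM. The gene model evm.model.chr11.1118 was 2.01-fold higher in layer 2 (adjusted p = 0.025), close to the fold minimum, and its call was lost without the 6 libraries (adjusted p = 0.055) and in 9 of the 18 fits that left out 1 library, with adjusted p up to 0.063. These 9 left out Alachua layer 2 replicate 1, Alachua layer 3 replicate 2, Granny Val layer 2 replicate 1 or 3, Granny Val layer 3 replicate 1 or 2, Supreme layer 2 replicate 1, or Supreme layer 3 replicate 1 or 2. The count of 990 became 2079 without the 6 libraries, with 952 shared. The balance of directions was not stable, with 946 higher and 1133 lower without the 6 libraries and 264 higher and 173 lower in the 25 libraries whose names begin with a number, and the higher ones also outnumbered the lower ones without Alachua layer 3 replicate 1. The fit of those 25 keeps all 6 libraries out of place and has 1 Granny Val library in each of these layers. The count of 990 became 550 and 636 without Alachua layer 2 replicates 1 and 2, and 1948 and 624 without Alachua layer 3 replicates 1 and 3.

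Layers 3 and 4 differed in 2 gene models, 1 in each direction, while 1237 had an unadjusted p under 0.05. The higher one in layer 3 was evm.model.chr18.808, at 4.12 ± 0.646 against 1.28 ± 1.06 CPM (SD, n = 9 each; adjusted p = 0.0067). Alachua had 4.54 ± 0.69 CPM in layer 3 and 0 counts in its 3 libraries of layer 4, of which 2 are out of place. The levels were 4.06 ± 0.326 and 1.79 ± 0.417 CPM in Granny Val and 3.76 ± 0.787 and 2.06 ± 0.752 CPM in Supreme (n = 3 each). The lower one was evm.model.chr5.476, at 18.6 ± 5.23 against 58.8 ± 41.5 CPM (log2 fold change -1.58, SE 0.26, adjusted p = 0.018). Neither met the rule for naming, and both were named because the count is small. Without the 6 libraries out of place 8 gene models were called, and evm.model.chr18.808 was no longer among them (adjusted p = 0.059), while DESeq2 called 206. Leaving out 1 library gave 10 calls without Alachua layer 3 replicate 1, 6 without Alachua layer 4 replicate 1, 4 without Granny Val layer 3 replicate 3, 5 without Granny Val layer 4 replicate 1, and 1 without Alachua layer 4 replicate 2, Granny Val layer 3 replicate 1 or 2, Granny Val layer 4 replicate 2 or 3, Supreme layer 3 replicate 1 or 2, or Supreme layer 4 replicate 2 or 3; the call of evm.model.chr5.476 was lost without each of the libraries listed for 1 call and without Alachua layer 3 replicate 3, 10 of the 18 fits, with adjusted p up to 0.089.

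Enrichment in a single layer was found mainly in layer 1, where 429 gene models were higher than in each of the other layers. One of them, evm.model.chr8.1099, had 30.3 ± 44.1 CPM in layer 1 (SD, n = 9) and 1.1 ± 3.75 CPM in the other layers (n = 27). Another, evm.model.chr3.1948, had 37.3 ± 30 against 7.18 ± 19 CPM; both were chosen after their values were seen. Without Supreme layer 2 replicate 1, at 19.5 and 97.7 CPM, the means of the other layers were 0.386 ± 0.718 and 3.7 ± 6.07 CPM (n = 26), and without Granny Val layer 1 replicate 3, at 140 CPM, evm.model.chr8.1099 was at 16.6 ± 16.6 CPM in layer 1 (n = 8). In layer 2 the single enriched gene model was evm.model.chr11.574, at 27.2 ± 13.5 against 11.4 ± 13.2 CPM (adjusted p = 0.016 for the contrast with the smallest fold). In Supreme, replicates 1, 2 and 3 of this gene model were at 62.4, 26.8 and 21.9 CPM in layer 1 and at 17, 46.2 and 44.3 CPM in layer 2, and replicate 1 is out of place in both layers. The edgeR fit found 0 enriched in layer 3 and 0 in layer 4. At an unadjusted p under 0.05 in each of the 3 contrasts, 262 and 86 gene models were higher there, and DESeq2 called 15 and 1. Without the 6 libraries 1003 gene models were enriched in layer 1, 397 of them shared, with 13 in layer 2 and 1 in layer 3.

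The count of 429 for layer 1 was 280 and 185 without Alachua layer 1 replicates 2 and 3, 168 and 147 without Alachua layer 2 replicates 2 and 3, 223 without Granny Val layer 1 replicate 3, 188 and 150 without Granny Val layer 2 replicates 1 and 2, 199 and 193 without Supreme layer 1 replicates 2 and 3, and 853, 121 and 129 without Supreme layer 2 replicates 1, 2 and 3. For layer 2 the count was 5 without Supreme layer 2 replicate 1, 3 without Alachua layer 2 replicate 3, Granny Val layer 2 replicate 3 or Supreme layer 1 replicate 1, and 2 without Alachua layer 1 replicate 1, layer 2 replicate 2, layer 3 replicate 1, layer 4 replicate 1 or layer 4 replicate 3, Granny Val layer 1 replicate 1, or Supreme layer 4 replicate 1 or 3. It was 1 for layer 3 without Alachua layer 3 replicate 1 or layer 4 replicate 1, and 1 for layer 4 without Alachua layer 4 replicate 3, Granny Val layer 4 replicate 1 or Supreme layer 2 replicate 3.

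**Figure D3:**
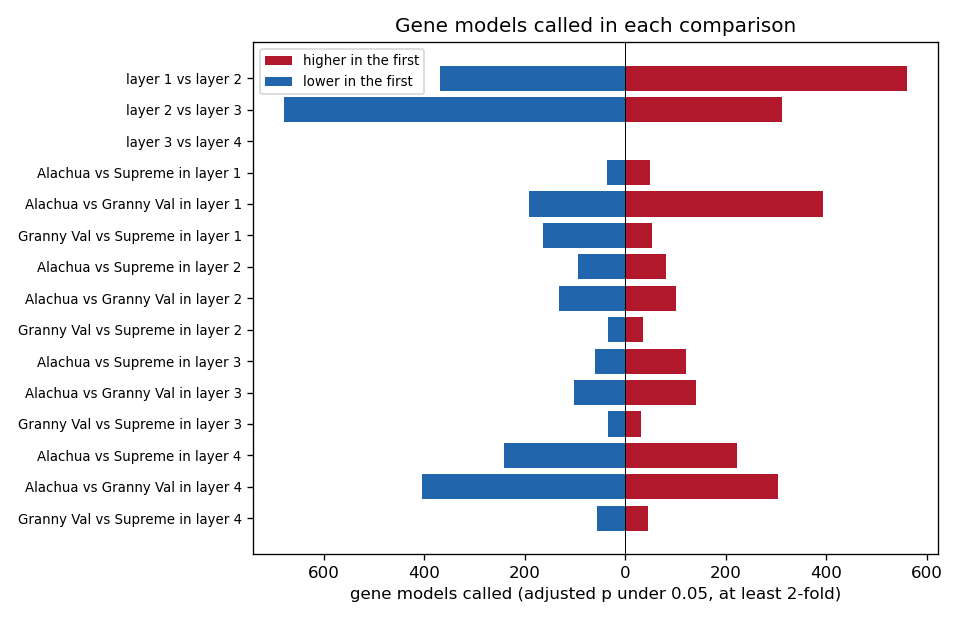
Number of gene models called in each comparison, with those higher in the group named first to the right of 0 and those lower to the left. Layers 1 and 2 differed in 928 gene models and layers 3 and 4 in 2.

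Of the 14 comparisons with unequal numbers higher and lower, the direction with more calls turned under at least 1 alternative in 11. It did not in the 3 others, which are Alachua against Granny Val and Granny Val against Supreme in layer 1 and Alachua against Supreme in layer 3. In the last, 68 were higher and 58 lower in Alachua without the 6 libraries out of place. The split was 54 and 44 without Alachua layer 3 replicate 1, which is out of place, and 159 and 35 without replicate 2. In each of the 12 comparisons of cultivars DESeq2 called more gene models than edgeR, between 338 and 1803. With the kind of library name as a covariate, 363, 113 and 133 gene models differed between Granny Val and Supreme in layers 1 to 3, and 569, 410 and 1302 between Alachua and Granny Val in layers 2 to 4. The 25 numbered libraries alone gave 79 and 91 for Alachua against Supreme in layers 2 and 3, and 248 for Alachua against Granny Val in layer 1. They hold 1 library of Granny Val in layer 2, 1 in layer 3 and 1 of Supreme in layer 4. Counts for comparisons with these groups are therefore not given.

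In layer 1, the outermost tissue, the cultivars with the thickest and the thinnest skin differed in 85 gene models, 49 higher in Alachua and 36 lower. The gene model evm.model.chr16.1566 had 68.3 ± 9.46 CPM in Alachua (SD, n = 3) and 1 count over the 3 Supreme libraries, a ratio of 10000 with a 95% counting interval from 1800 to 396000 (adjusted p = 1e-09). At 26.1 ± 6.35 CPM in Alachua, evm.model.chr8.717 had 0 counts in Supreme, at least 1280-fold higher (adjusted p = 0.00016). In the other direction evm.model.chr6.1949 had 0 counts in Alachua and 31.2 ± 9.71 CPM in Supreme, at least 1180-fold higher there (adjusted p = 0.0029). With 0 counts in Alachua, evm.model.chr10.1903 had 36.2 ± 27.9 CPM in Supreme, at least 1370-fold higher (adjusted p = 0.0062), but was not called in the 25 numbered libraries alone (adjusted p = 0.095). The 85 calls became 49 and 52 without Alachua layer 1 replicates 2 and 3, and 51, 55 and 46 without Supreme layer 1 replicates 1, 2 and 3.

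Alachua and Granny Val differed in 585 gene models in layer 1, 394 higher in Alachua and 191 lower. Against 0 counts in Granny Val, evm.model.chr8.717 was at least 1210-fold higher in Alachua. Against 0 counts in Alachua, evm.model.chr6.1949 had 24.4 ± 7.18 CPM in Granny Val, at least 923-fold higher (SD, n = 3). The rule also named evm.model.chr8.1708, with 70.3 ± 27.8 CPM in Alachua and 0 counts in Granny Val (at least 3260-fold), and evm.model.chr18.2158, with 26 ± 5.99 CPM in Granny Val and 0 counts in Alachua (at least 987-fold). The call of evm.model.chr8.1708 was lost without Alachua replicate 1 or any 1 of the 3 Granny Val libraries (adjusted p up to 0.1), and that of evm.model.chr18.2158 without any 1 of the 6 libraries (adjusted p up to 0.14). Between Granny Val and Supreme 53 gene models were higher and 163 lower. With 66.9 ± 5.82 CPM in Granny Val and 0 counts in Supreme, evm.model.chr7.1374 was at least 3280-fold higher (adjusted p = 2.2e-10), and evm.model.chr18.3740, with 13.8 ± 2.84 CPM, at least 674-fold higher. Higher in Supreme were evm.model.chr16.352, at 21.4 ± 1.85 CPM against 0 counts (at least 991-fold, adjusted p = 1e-05), and evm.model.chr4.764, at 18.7 ± 9.83 CPM against 0 counts (at least 867-fold), whose call was lost without any 1 of the 3 Granny Val libraries (adjusted p up to 0.091).

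For Alachua against Granny Val in layer 1 the 585 calls became 183 without Alachua replicate 1 and 208, 229 and 273 without Granny Val replicates 1, 2 and 3. For Granny Val against Supreme the 216 calls became 106, 103 and 113 without Granny Val replicates 1, 2 and 3 and 89 without Supreme replicate 1.

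In layer 2 Alachua and Supreme differed in 175 gene models, 81 higher and 94 lower in Alachua. There evm.model.chr16.1566 had 50.9 ± 7.7 CPM in Alachua (SD, n = 3) and 0 counts in Supreme, at least 2220-fold higher (adjusted p = 1.3e-09). Conversely evm.model.chr6.1949 had 0 counts in Alachua and 31.4 ± 10.7 CPM in Supreme, at least 1340-fold higher (adjusted p = 0.0016). At 42.9 ± 71.8 CPM in Alachua against 0 counts, evm.model.chr2.765 was at least 1870-fold higher. Without Alachua replicate 3, at 126 CPM, it was at 1.43 ± 0.603 CPM, at least 62-fold higher (n = 2), and its call was lost without Alachua replicate 3 or any 1 of the 3 Supreme libraries (adjusted p up to 0.28). At 28.8 ± 48.6 CPM in Supreme against 0 counts, evm.model.chr5.936 was at least 1230-fold higher there. Without Supreme replicate 1, at 85 CPM, it was at 0.74 ± 0.19 CPM, at least 31.5-fold higher (n = 2), and its call was lost without Supreme replicate 1 or any 1 of the 3 Alachua libraries (adjusted p up to 0.3). Without the 6 libraries out of place 82 gene models were called, 69 of them shared, and evm.model.chr2.765 (adjusted p = 0.086) and evm.model.chr5.936 (adjusted p = 0.24) were not. A fit of the 9 libraries of layer 2 alone called 50. The 175 calls became 83 and 89 without Alachua replicates 2 and 3, and 91, 107 and 115 without Supreme replicates 1, 2 and 3.

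Between Alachua and Granny Val in layer 2, 100 gene models were higher and 132 lower in Alachua. Among them evm.model.chr6.245 had 55.6 ± 12.9 CPM in Alachua and 0 counts in Granny Val, at least 2050-fold higher (adjusted p = 3.1e-08), and evm.model.chr16.1566 was at least 1880-fold higher. Lower in Alachua, at 0 counts, were evm.model.chr6.1949, with 12.5 ± 7.14 CPM in Granny Val (at least 532-fold), and evm.model.chr2.1083, with 11 ± 8.7 CPM (at least 470-fold), which was at 6.11 ± 2.47 CPM without Granny Val replicate 2, at least 260-fold higher (n = 2). The latter call was lost without any 1 of the 6 libraries (adjusted p up to 0.12) and without the 6 libraries out of place (adjusted p = 0.06). Granny Val and Supreme differed in 71 gene models in this layer, 36 higher and 35 lower in Granny Val. The level of evm.model.chr7.1374 was 259 ± 111 CPM in Granny Val against 0 counts, at least 11300-fold higher (adjusted p = 3.6e-11), and that of evm.model.chr2.849 was 25.9 ± 7.48 CPM, at least 1130-fold higher. Higher in Supreme were evm.model.chr10.1903, at 16.8 ± 23.8 CPM (at least 621-fold), and evm.model.chr9.1282, at 13.3 ± 3.33 CPM (at least 490-fold). Without Supreme replicate 1, at 44.3 CPM and out of place, evm.model.chr10.1903 was at 3.09 ± 0.425 CPM, at least 114-fold higher (n = 2). Both lost their calls without any 1 of the 3 Granny Val libraries, and evm.model.chr9.1282 also without Supreme replicate 2, with adjusted p up to 0.069 and 0.098. The 232 calls for Alachua against Granny Val became 151, 120 and 116 without Alachua replicates 1, 2 and 3 and 107 without Granny Val replicate 3. The 71 for Granny Val against Supreme became 34, 45 and 45 without Granny Val replicates 1, 2 and 3 and 30 and 46 without Supreme replicates 2 and 3. Fits of the 9 libraries of layer 2 alone called 61 and 12 for these comparisons.

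Genes whose level follows skin thickness from Alachua over Granny Val to Supreme were sought in layers 1 and 2. In the edgeR fit 0 gene models were ordered in this way in layer 1 and 0 in layer 2. At an unadjusted p under 0.05 in each of the 3 contrasts there were 11 and 24, and DESeq2 gave 1 and 3. The count for layer 1 was 1 without Granny Val layer 1 replicate 3.

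In layer 3, 120 gene models were higher and 61 lower in Alachua than in Supreme. The gene model evm.model.chr2.328 was at 0.489 ± 0.802 CPM in Alachua and at 403 ± 149 CPM in Supreme (SD, n = 3; log2 fold change -9.76, SE 1.45, adjusted p = 0.00033). In Granny Val it was at 247 ± 76.1 CPM, also far above Alachua (log2 fold change -9.06, adjusted p = 0.00057). The mean in layer 3 of Alachua was 0.0263 ± 0.0373 CPM without replicate 2 (n = 2). Its level in Alachua stayed between 0.489 and 1.08 CPM on average in all 4 layers. Higher in Alachua were evm.model.chr4.2350, at 32.1 ± 20 CPM against 0 counts in Supreme (at least 1790-fold, adjusted p = 0.0012), and evm.model.chr16.1566, at 59.8 ± 19.3 CPM against 1 count. Without Alachua replicate 1, at 54.1 CPM and out of place, evm.model.chr4.2350 was at 21.1 ± 8.4 CPM, at least 1180-fold higher (n = 2). Also lower was evm.model.chr16.352, with 2 counts in Alachua and 23.7 ± 5.27 CPM in Supreme, a ratio of 1670 (95% counting interval 463 to 13800). The 181 calls became 98 and 274 without Alachua replicates 1 and 3, and 96, 58 and 93 without Supreme replicates 1, 2 and 3. A fit of the 9 libraries of layer 3 alone called 19, and DESeq2 called 871.

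Alachua had 140 gene models higher and 102 lower than Granny Val in layer 3. With 60.2 ± 15.7 CPM against 1 count, evm.model.chr6.245 had a ratio of 8310 (95% counting interval 1490 to 328000), and evm.model.chr16.1566, also against 1 count, a ratio of 8250 (1480 to 326000). Beside evm.model.chr2.328, evm.model.chr18.3740 was lower in Alachua, at 0 counts against 20.5 ± 4.73 CPM (at least 964-fold). Granny Val and Supreme differed in 66 gene models, 32 higher and 34 lower. At 131 ± 57.7 CPM in Granny Val, evm.model.chr7.1374 was at least 7310-fold higher than in Supreme (adjusted p = 6.7e-11), and evm.model.chr18.3740 at least 1150-fold. Lower in Granny Val were evm.model.chr16.352, with 1 count (ratio 3270, 95% counting interval 587 to 129000), and evm.model.chr4.2498, also with 1 count, against 10.3 ± 6.32 CPM in Supreme (ratio 1430, 256 to 56400). The latter call, with adjusted p = 0.049, was lost without any 1 of the 6 libraries (adjusted p up to 0.27), and without Supreme replicate 1 the level in Supreme was 6.71 ± 0.697 CPM. The 242 calls became 134 without Alachua replicate 1 and 111, 154 and 82 without Granny Val replicates 1, 2 and 3. The 66 calls became 37 and 37 without Granny Val replicates 1 and 3, 34 and 43 without Supreme replicates 2 and 3, and 142 without the 6 libraries out of place, 64 of them shared. Fits of the 9 libraries of layer 3 alone called 34 and 9 for these comparisons, and DESeq2 called 1054 and 387.

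Layer 4 had 464 calls between Alachua and Supreme, 223 higher and 241 lower in Alachua. Higher in Alachua were evm.model.chr4.2350, at 54 ± 19.1 CPM against 1 count in Supreme (ratio 9150, 95% counting interval 1640 to 361000; SD, n = 3), and evm.model.chr16.1566, at 58.8 ± 8.76 CPM against 1 count. At 0 counts in Alachua, evm.model.chr16.1891 had 62.5 ± 49.5 CPM in Supreme (at least 2860-fold) and evm.model.chr11.393 had 51.3 ± 15.7 CPM (at least 2340-fold). Of the 3 Alachua libraries in this layer 2 are out of place, and without the 6 libraries there were 96 calls, 62 of them shared. That fit has 1 Alachua library in this layer. Neither evm.model.chr16.1891 (log2 fold change -14.5) nor evm.model.chr11.393 (-14.22) was called in it. The remaining library also had 0 counts of both. In layer 2 of Supreme, evm.model.chr11.393 was at 0.0972 ± 0.168 CPM and evm.model.chr16.1891 at 20.9 ± 6.22 CPM. In layer 3, evm.model.chr11.393 was at 3.72 and 3.81 CPM in Alachua replicates 2 and 3, against 32.9 ± 16.8 CPM in Supreme. The 2 libraries out of place lay nearest layer 2. A wrong layer and a difference of cultivar therefore cannot be told apart for evm.model.chr11.393. The 464 calls became 152 and 164 without Alachua replicates 2 and 3, either of which also ended the call of evm.model.chr11.393 (adjusted p up to 0.057), and 176 and 213 without Supreme replicates 2 and 3.

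In layer 4, 304 gene models were higher and 404 lower in Alachua than in Granny Val. Against 0 counts in Granny Val, evm.model.chr4.2350 was at least 2460-fold higher in Alachua (adjusted p = 0.00039), and evm.model.chr8.717, at 11 ± 4.53 CPM, at least 498-fold higher. At 0 counts in Alachua were evm.model.chr10.231, with 34.9 ± 33.6 CPM in Granny Val (at least 1590-fold), and evm.model.chr10.918, with 29.6 ± 24.4 CPM (at least 1350-fold). Without Granny Val replicate 1 the former was at 18 ± 23.6 CPM, at least 824-fold higher (n = 2). Without the 6 libraries, with 1 Alachua library in this layer, 136 gene models were called, 90 of them shared. The calls of evm.model.chr10.231 and evm.model.chr10.918 were lost in that fit (log2 fold change -13.65 and -13.41). The remaining Alachua library also had 0 counts of both. In layer 3, evm.model.chr10.231 was at 30.6 and 71.1 CPM in Alachua replicates 2 and 3. In layer 2 of Granny Val it was at 0.203 ± 0.326 CPM. The Alachua libraries of layer 4 out of place lay nearest layer 2. A wrong layer and a difference of cultivar therefore cannot be told apart for evm.model.chr10.231. The level of evm.model.chr10.918 was 0.0644 ± 0.112 CPM in layer 3 of Alachua. The 708 calls became 243 and 257 without Alachua replicates 2 and 3, either of which also ended the call of evm.model.chr10.231 (adjusted p up to 0.065), and 418 and 355 without Granny Val replicates 1 and 2; the median log2 fold change over all gene models was -0.11.

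Between Granny Val and Supreme, layer 4 had 45 gene models higher and 56 lower in Granny Val. The level of evm.model.chr7.1374 was 90.8 ± 28.6 CPM in Granny Val against 0 counts (at least 5120-fold, adjusted p = 1.1e-10). With 1 count in Granny Val and 19.3 ± 5.49 CPM in Supreme, evm.model.chr17.377 had a ratio of 2640 (95% counting interval 473 to 104000; adjusted p = 3.8e-06). Also named were evm.model.chr2.1083, at 28.2 ± 25.7 CPM in Granny Val against 0 counts (at least 1590-fold), and evm.model.chr16.1891, at 0.0248 ± 0.0429 against 62.5 ± 49.5 CPM. The former lost its call without Granny Val replicate 2 or Supreme replicate 2 or 3, the latter without Granny Val replicate 1 or 2 or Supreme replicate 2, with adjusted p up to 0.13 for each. Without Granny Val replicate 2, evm.model.chr2.1083 was at 14.9 ± 16.1 CPM there, at least 840-fold higher (n = 2), and without Granny Val replicate 3, evm.model.chr16.1891 had 0 counts there. The 101 calls became 54, 40 and 152 without Granny Val replicates 1, 2 and 3, 311, 39 and 41 without Supreme replicates 1, 2 and 3, and 220 without the 6 libraries out of place, with all 101 shared. A fit of the 9 libraries of layer 4 alone called 41.

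**Figure D4:**
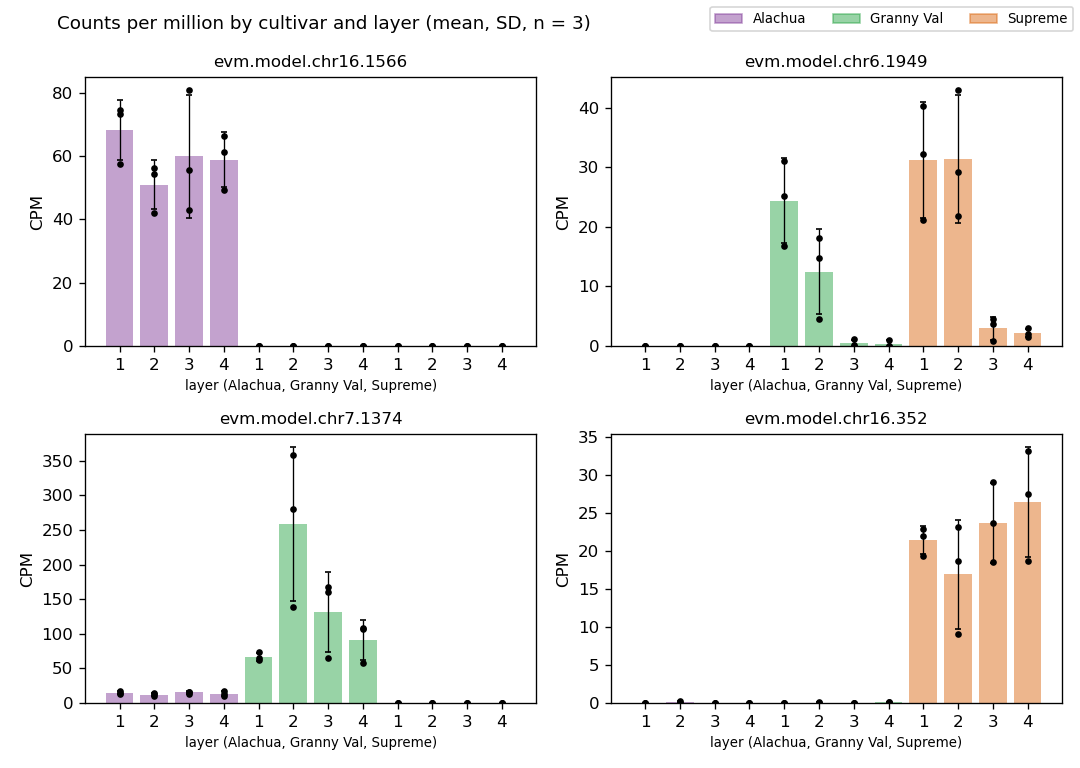
CPM of 4 gene models named in several cultivar comparisons, by cultivar (colour) and layer (horizontal axis). Bars give the mean, lines the SD and points the 3 libraries; evm.model.chr16.1566 was at 50.9 to 68.3 CPM on average in the 4 layers of Alachua.

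Differences between cultivars recurred across layers. In all 4 layers 28 gene models were higher and 16 lower in Alachua than in Supreme, 39 were higher and 25 lower in Alachua than in Granny Val, and 12 were higher and 13 lower in Granny Val than in Supreme. In none of the 3 pairs of cultivars was a gene model called higher in 1 layer and lower in another (0 cases). The levels of the 4 layers came from different libraries, but 1 model supplied the spread of each gene model for all layers, so that the lists are not independent and no chance level is given.

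Whether the step from layer 2 to layer 3 differed between Alachua and Supreme was tested as an interaction. The edgeR test called 0 gene models, with 2253 at an unadjusted p under 0.05, and DESeq2 called 874. The count was 201 and 232 without Alachua layer 3 replicates 2 and 3, and 1 and 75 without Supreme layer 2 replicates 1 and 3. Without Alachua layer 3 replicate 2 or 3, replicate 1, which is out of place, is 1 of 2 libraries in that group. Without the 6 libraries out of place the count was 1.

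The names of 25 libraries begin with a number and those of 11 do not, and the labels do not say what the number stands for. A fit of the 25 alone keeps all 6 libraries out of place. In it Granny Val has 1 library in layer 2 and 1 in layer 3, and Supreme has 1 in layer 4. Changes in that fit therefore cannot be assigned to the kind of name. Among the 25 numbered libraries alone, 455 gene models were called between layers 1 and 2, 437 between layers 2 and 3 and 114 between layers 3 and 4, and 39 were enriched in layer 1. The first 3 of these lists shared 163, 69 and 0 gene models with those from all libraries, and the 114 were 1 higher and 113 lower in layer 3. Among the 24 libraries of Alachua and Supreme, 6 of the 18 numbered and 0 of the 6 unnumbered ones were out of place, which is no established link (Fisher's exact test, two-sided p = 0.277). With the kind of name as a covariate over all 36 libraries, the counts for these 4 results stayed within 1.5 times, while 7 of the 22 counts did not, 6 of them between cultivars, as given ahead of those comparisons. The 11 other libraries were not fitted on their own.

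Of the 63 named calls, 19 were lost in the 25 numbered libraries alone. Between layers these were evm.model.chr8.1635 and evm.model.chr6.386, given above, evm.model.chr11.1118 (log2 fold change 0.84), evm.model.chr18.808 (4.45) and evm.model.chr5.476 (-1.29). In layer 1 they were evm.model.chr10.1903, given above, and, between Alachua and Granny Val, evm.model.chr8.1708 (adjusted p = 0.09) and evm.model.chr18.2158 (0.18). In layer 2 they were evm.model.chr2.765 (adjusted p = 0.21) and evm.model.chr5.936 (0.26) between Alachua and Supreme. The other calls lost in layer 2 have 1 numbered library of Granny Val, so only the log2 fold change in that fit is given. These were evm.model.chr2.1083 (-10.62) between Alachua and Granny Val, and evm.model.chr10.1903 (-12.57) and evm.model.chr9.1282 (-12.23) between Granny Val and Supreme. In layer 3 it was evm.model.chr4.2498 (log2 fold change -11.24) between Granny Val and Supreme, again with 1 numbered library of Granny Val. Layer 4 has 1 numbered library of Supreme. The calls lost there were evm.model.chr4.2350 (log2 fold change 11.16), evm.model.chr16.1891 (-11.4) and evm.model.chr11.393 (-13.95) between Alachua and Supreme. Between Granny Val and Supreme they were evm.model.chr2.1083 (13.34) and evm.model.chr16.1891 (-11.4). With 1 library in a group, a lost call does not show that the difference shrank. The contrasts between neighbouring layers include such groups too.

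Fits of the 9 libraries of a layer alone lost 11 of the 48 calls between cultivars. They were evm.model.chr4.764 between Granny Val and Supreme in layer 1 (adjusted p = 0.055), evm.model.chr2.765 (0.18) and evm.model.chr5.936 (0.2) between Alachua and Supreme in layer 2, evm.model.chr2.1083 between Alachua and Granny Val in layer 2 (0.072), and evm.model.chr10.1903 (0.29) and evm.model.chr9.1282 (0.059) between Granny Val and Supreme in layer 2. In layer 3 they were evm.model.chr4.2350 and evm.model.chr2.328 between Alachua and Supreme (0.055 each), evm.model.chr2.328 between Alachua and Granny Val (0.05 after rounding), and evm.model.chr4.2498 between Granny Val and Supreme (0.17). In layer 4 it was evm.model.chr2.1083 between Granny Val and Supreme (0.078). Granny Val alone lost 7 of 15 calls between layers, which beside evm.model.chr6.386 and evm.model.chr1.1412 were evm.model.chr11.1118 (0.58), evm.model.chr11.1754 (0.059), evm.model.chr2.753 between layers 2 and 3, not described above (0.11), evm.model.chr18.808 (1) and evm.model.chr5.476 (1). The call of evm.model.chr11.1118 was also lost with DESeq2 (0.0067), RLE scaling (0.029), no filter on low counts (0.033) and the covariate (0.013), each time by falling below 2-fold. DESeq2 lost evm.model.chr2.1083 between Alachua and Granny Val in layer 2 (0.051), and the newer edgeR fit lost evm.model.chr10.1903 between Granny Val and Supreme in layer 2 (0.075).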

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

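The tests of the labels in this part were chosen after the scores of the libraries had been seen. Within the 9 libraries of each labelled layer, 3 libraries stood apart from the rest in a layer score. Supreme layer 2 replicate 1 had a layer 1 score of 3.18 (log2 units above the Granny Val mean), with a gap to the nearest other library that was 0.69 of the range of the 9. Alachua layer 2 replicate 3 had an inner score of 1.23 (gap ratio 0.65). Alachua layer 3 replicate 1 had a layer 1 score of 2.07 (gap ratio 0.82) and an inner score of -3.19 (gap ratio 0.88). These ratios exceed Dixon's 95% critical value for 9 libraries, which chance passes in about 1 of 20 groups; the gap was tested 16 times (4 layers, 2 scores, both ends) and 4 passed. The 9 libraries of a layer mix 3 cultivars, so this rate is only a guide. A further 3 libraries lay nearest another layer without such a gap: Supreme layer 1 replicate 1, with a layer 1 score of -0.01, and Alachua layer 4 replicates 2 and 3, with inner scores of -2.18 and -2.47. The names of all 6 begin with a number, as do 18 of the 24 tested (Fisher's exact test, two-sided p = 0.277). The gene sets were made from Granny Val, whose own libraries therefore could not be tested.

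An exchange of labels with layers 1 and 2 was excluded as the cause for all 3 Alachua libraries of layers 3 and 4 together, since it needs 3 partners and 1 library labelled layer 1 or 2 lay nearest the inner layers. Outer tissue mixed into samples of layers 3 and 4 was excluded only where a sizeable share of inner tissue remained, since the highest of their inner scores was -2.18, inside the range of the 7 layer 2 libraries (-2.73 to -1.6); dissection that left little inner tissue stays open. An exchange of Supreme layer 1 replicate 1 with layer 2 replicate 1 may explain that pair, since the score of 3.18 lay inside the range of the other layer 1 libraries (1.41 to 3.61) and the partner lay nearest layer 2, although its layer 1 score of -0.01 was just above the range of the 7 layer 2 libraries (-1.36 to -0.19). An exchange of Alachua layer 2 replicate 3 with layer 4 replicate 3 may explain that pair, since the score of 1.23 lay inside the range of layer 4 (0.47 to 3.26), but layer 4 replicate 2 would serve equally as the partner. A layer 4 of Alachua that resembles layer 2 as a group, a difference of cultivar, and wrong labels cannot be told apart, because the 1 remaining library of that group, with an inner score of 0.47, is too few.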

How the results depend on the processing

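The fits without the 6 libraries out of place, of the Granny Val libraries alone and with the newer edgeR method were chosen after the data were seen, and the first of these is circular in that it leaves out libraries by the expression measured in them. Depth limits genes near the floor of 3 counts, between 0.0423 and 0.144 CPM per library. The 22 lists of genes were not run, and Granny Val alone gives no comparison of cultivars. RLE scaling and the absence of a filter on low counts kept all 22 counts within 1.5 times. Of 1125 refits of the 63 named combinations of gene model and comparison, 996 kept the call with its direction, 129 lost the call and 0 reversed. For the counts given next, the cause was not tested unless stated.

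With no fold minimum, which by construction adds calls, 1482 gene models differed between layers 1 and 2, 4 were enriched in layer 2 and 1 in layer 4. DESeq2 called 1566 between layers 1 and 2, 1496 between layers 2 and 3 and 206 between layers 3 and 4, with 725, 7, 15 and 1 enriched in layers 1 to 4. In layers 1 to 4 it called 338, 1124, 871 and 1445 between Alachua and Supreme, 1379, 861, 1054 and 1803 between Alachua and Granny Val, and 754, 521, 387 and 666 between Granny Val and Supreme. It ordered 1 gene model in layer 1 and 3 in layer 2, and its interaction count was 874. The newer edgeR fit called 1469 between layers 1 and 2, with 917, 3 and 1 enriched in layers 1 to 3. In layers 1 to 4 it called 195, 503, 516 and 940 between Alachua and Supreme, 995, 427, 563 and 1368 between Alachua and Granny Val, and 392, 215, 142 and 315 between Granny Val and Supreme, with 1 ordered in layer 1 and 381 in the interaction.

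With the kind of library name as a covariate, 3 gene models were enriched in layer 2. Granny Val and Supreme differed in 363, 113 and 133 in layers 1 to 3, and Alachua and Granny Val in 569, 410 and 1302 in layers 2 to 4. The numbered libraries alone gave 455, 437 and 114 for the 3 neighbouring pairs of layers and 39 enriched in layer 1. They gave 79, 91 and 68 for Alachua against Supreme in layers 2 to 4, 248, 1073 and 871 for Alachua against Granny Val in layers 1 to 3, and 787, 601 and 12 for Granny Val against Supreme in layers 2 to 4. The 9 libraries of a layer alone, with fewer residual degrees of freedom, gave 50 and 19 for Alachua against Supreme in layers 2 and 3, 61 and 34 for Alachua against Granny Val there, and 12, 9 and 41 for Granny Val against Supreme in layers 2 to 4.

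A replicate block gave 615, 605 and 0 for the 3 neighbouring pairs of layers; it was kept out of the report because residuals of libraries with 1 number were not alike, with a correlation over 0.1 in 10 of 54 pairs, a median of -0.01, and the best match at the own number in 6 of 36 cases. The 3 Granny Val pairs of layers 2 and 3 were at 0.26, 0.29 and 0.31, those of Alachua at 0.42, -0.25 and 0.27 and those of Supreme at 0.01, 0.07 and 0. In Granny Val, replicate 3 is the only numbered library of layer 2 and of layer 3. Pairing and the kind of library name therefore cannot be told apart there. Replicate 3 of its layer 4 is unnumbered, with -0.28 and -0.32 against layers 2 and 3. Under the block 6 of the 63 named calls were lost. Between layers these were evm.model.chr11.1118 for layers 2 and 3, and evm.model.chr18.808 and evm.model.chr5.476 for layers 3 and 4. Between Alachua and Supreme in layer 2 they were evm.model.chr2.765 and evm.model.chr5.936. Between Granny Val and Supreme in layer 3 it was evm.model.chr4.2498. Without the 6 libraries out of place the counts were 2082 between layers 1 and 2, 2079 between layers 2 and 3 and 8 between layers 3 and 4, with 1003, 13 and 1 enriched in layers 1 to 3. They were 82 and 96 for Alachua against Supreme in layers 2 and 4, 136 for Alachua against Granny Val in layer 4, 142 and 220 for Granny Val against Supreme in layers 3 and 4, and 1 for the interaction. In Granny Val alone 497 gene models differed between layers 2 and 3, 345 of them shared, and 0 between layers 3 and 4, with 8 enriched in layer 2; the 978 between layers 1 and 2 shared 457.

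Leaving out each library in turn gave 363 to 1752 calls between layers 1 and 2, 550 to 1948 between layers 2 and 3 and 1 to 10 between layers 3 and 4. Enriched gene models numbered 121 to 853 in layer 1, 1 to 5 in layer 2, 0 to 1 in layer 3 and 0 to 1 in layer 4. In layers 1 to 4 Alachua against Supreme gave 46 to 72, 83 to 140, 58 to 274 and 152 to 640, Alachua against Granny Val 183 to 518, 107 to 186, 82 to 282 and 243 to 893, and Granny Val against Supreme 89 to 200, 30 to 48, 34 to 48 and 39 to 311. The ordered counts were 0 to 1 in layer 1 and 0 to 0 in layer 2, and the interaction 0 to 232. The report names each library that moved a count by more than 1.5 times. Where a fit leaves 1 or 2 libraries in a group, they are assumed to vary like the other groups. The fit without the 6 libraries out of place leaves 1 in layer 4 of Alachua. That of the numbered libraries leaves 1 in layer 2 and 1 in layer 3 of Granny Val and 1 in layer 4 of Supreme.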

Other observations

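The stretches of gene models, the gene models limited to some cultivars, the position of Granny Val, the regroupings and the test of depth on the numbered libraries were chosen after results were seen. Windows of 20 tested gene models in the order of their running numbers, 962 in all, were tested for called gene models, with 19 of 27898 tests past the adjusted threshold. That this order follows the chromosome is an assumption, and neighbours with similar sequences can share reads. On chromosome 16, 12 of the 20 tested models numbered 1785 to 1822 were higher in layer 1 than in layer 2 (adjusted p = 4.7e-10), and 12 were enriched in layer 1 (adjusted p = 3.9e-11). Their summed level was 1600 ± 988 CPM in layer 1, 635 ± 598 in layer 2, 513 ± 191 in layer 3 and 419 ± 110 in layer 4 (SD, n = 9 each). Over the whole of chromosome 16, 51 of 764 tested models were higher in layer 1 than in layer 2, 6.68% against 2.75% elsewhere (adjusted p = 2e-05), and 3 windows of 20 models held 12, 7 and 6 of these 51. On chromosome 4, 6 of the 20 models numbered 171 to 210 were lower in Alachua than in Granny Val in layer 4 (adjusted p = 0.017), with a summed level over all layers of 212 ± 73.2 CPM in Alachua, 879 ± 972 in Granny Val and 675 ± 366 in Supreme (SD, n = 12 each). On chromosome 1, 3 of the 20 models numbered 1832 to 1884 were higher in Granny Val than in Supreme in each of the 4 layers (adjusted p between 0.017 and 0.036), but the summed level of the window was 843 ± 98.2 CPM in Granny Val and 860 ± 56.8 in Supreme (SD, n = 12 each). Neighbouring models were called in the same direction in 95 pairs for layer 1 against layer 2, against a mean of 23.2 and a highest value of 39 over shuffled orders (permutation test, one-sided p = 0.001, the smallest these shuffles can give).

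Granny Val, with the intermediate skin, lay between Alachua and Supreme in mean level in 43 of the 85 gene models called between those cultivars in layer 1 and in 117 of the 175 in layer 2. It lay nearer to Supreme in 54 and 128 of them. Choosing gene models by a difference between Alachua and Supreme favours a position between them, so these shares have no simple chance level.

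A few gene models were counted in every library of some cultivars and at 3 counts or fewer in every library of another. In Alachua alone there were 4, among them evm.model.chr16.1566 at 59.5 ± 12.2 CPM (SD, n = 12) and evm.model.chr15.1965 at 7.76 ± 4.64 CPM against 0 counts in the 24 other libraries, at least 2940-fold higher. In Granny Val alone there was 1, evm.model.chr18.3740 at 18.7 ± 6.57 CPM. At the low level in Supreme alone were 3, among them evm.model.chr7.1374, with 75.3 ± 90.9 CPM in the 24 libraries of the other cultivars and 0 counts in the 12 of Supreme, at least 15400-fold higher. That bound pools Granny Val, with layer means of 66.9 to 259 CPM, and Alachua, with layer means of 11.9 to 15.1 CPM. By such sets, made without the library in question, all 36 libraries went to their labelled cultivar.

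Depth was excluded as the cause of these differences, since at the mean level of the other side the lowest number of counts expected in a library was 155. Loss of a stretch with several expressed models and single changes cannot be told apart, because 4 of the 16 neighbouring tested models were also at 3 counts or fewer, against 0.0939 expected from all tested models, and neighbours can be copies of each other. A difference in sequence from the reference, a lost copy of the single model and a lack of transcription, which a difference between cultivars could bring, cannot be told apart from gene counts, and the 1 or more counts on the low side of 6 of the 8 models may be stray reads.

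The 11 libraries whose names have no leading number detected a median of 18990 gene models (16950 to 19480) and the 25 numbered libraries 16120 (13960 to 17960). Depth was excluded as the cause, since after thinning to 19057538 counts the medians were 18110 and 15960 and in 8 of the 8 groups with both kinds every unnumbered library exceeded every numbered one. Fewer distinct molecules in the numbered libraries may explain the gap: at summed counts of 4 to 10, the squared difference between libraries of a group over their sum averaged 6.19 ± 0.326 in 8 numbered pairs and 2.96 ± 0.579 in 3 unnumbered pairs (SD), a ratio of 2.09, where the spread at 400 to 1000 counts would give 1.32 and 1.26; pairs with a library out of place were left out, and no group has pairs of both kinds, so the groups differ as well. Reads leaking in from other libraries and low expression cannot be told apart as a further part, since 15 stray counts at 3 gene models gave an expected 227 gene models against an excess of 1127. The kinds of name are spread unevenly over the tissues, with 1 unnumbered library of 9 in layer 1, 3, 4 and 3 in layers 2 to 4 and 0 in 4 of the 12 groups, so the pooled medians and this excess differ in layer and cultivar as well; no biological difference was tested.

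Labels were exchanged within cultivars to see whether other groupings give as many calls. For layer 1 against layer 2, 1 of 41 groupings, the real one, gave 928 or more and the highest other gave 901. That other grouping exchanged replicate 1 of Supreme and replicate 2 of Granny Val between the layers, and the next gave 82. Its Supreme exchange is the one that may explain that pair of libraries out of place. The real grouping also gave the most for layer 2 against layer 3 (1 of 41, 990 against 96). So it did for enrichment in layer 1 (1 of 41, 429 against 0). A share of 1 of 41 is the smallest these groupings can give. It was not adjusted for the 22 results with a count, so it does not exclude chance over all of them. For enrichment in layer 2, 1 of 41 groupings, the real one, gave 1 and the others gave 0, but a single call does not exclude chance, since a regrouping also gave 1 for layer 3. Chance was not excluded for layer 3 against layer 4, where 10 of 41 groupings gave 2 or more and the highest gave 32. The cause of such counts was not tested. For counts of 0 every grouping is as large: 41 of 41 for enrichment in layer 3 (highest other 1), in layer 4 (0) and for the interaction (0), and 21 of 21 for the ordered genes in both layers (0 each).

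The 12 comparisons of cultivars have 10 groupings each, too few for a share under 0.05, and in each 1 of the 10, the real one, gave as many calls. The real counts for Alachua against Supreme in layers 1 to 4 were 85, 175, 181 and 464, with highest others of 0 in each. For Alachua against Granny Val they were 585, 232, 242 and 708, with highest others of 2, 0, 8 and 2. For Granny Val against Supreme they were 216, 71, 66 and 101, with highest others of 1, 0, 0 and 37.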
